A study of Homo sapiens with 4 samples.

How the data were processed

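RNA from SKOV3, a human ovarian cancer cell line, was profiled after exposure to the ginseng saponin 20(S)-Rg3 at 80 µg/mL for 24 h and in control cells. Each group held 2 libraries, and groups were read from the treatment label of each sample. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted, and cDNA libraries were made with a total RNA kit that does not select for polyadenylated RNA. The labels describe the RNA behind each library as pooled and do not say whether the 2 libraries of a group came from separate cultures. The p-values of single genes therefore measure the spread between these 4 libraries, which may be technical. The series text and the library protocol name sequencing instruments of different makers, and which of these was used was left open.

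The deposited table held raw read counts per gene symbol, as whole numbers that the authors had not normalised, with 40205 genes and one column per library. Per the submitters' processing notes the genome build was GRCh37. The aligner, the counting tool, the gene annotation and the strand setting were not given in the sources used here. Counts of a gene may therefore include reads of an overlapping antisense gene, and reads from near-identical copies may have been assigned to any of the copies. Every row had a gene name. Of these genes 14537 had no count in any library and stayed out of every test.

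Gene classes came from an NCBI RefSeq gene table of a newer human assembly, which was used only for names and classes, so no coordinates are given and no check of gene length or GC content was made. Of the symbols, 31821 matched directly, 3481 by gene number in a LOC symbol and 2368 by a unique older symbol. Another 9 were classed by symbol pattern and 2526 remained without a class. This gave 19208 protein-coding genes, 11983 pseudogenes and 4088 long non-coding RNA genes, antisense RNA included.

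Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 16323 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test with treatment as the only term and 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. Levels are CPM values from edgeR, counts scaled to a common library size after TMM. Standard errors of log2 fold changes were derived from the F statistic. Gene lists were tested with camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and adjustment over the lists with at least 5 tested members. At the preset correlation camera compares members with other genes, so its p-values rest on the spread across genes and on that assumed correlation. The same lists were tested with an estimated correlation and with fry. Members of each list were also adjusted over the list alone, with no correction across the lists, so a member that passes this way need not pass over all genes.

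The design, the alternatives, 32 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall or, with fewer than 10 called, the 10 genes with the smallest p. For long non-coding RNA it took 5 genes per direction in the same way. It also took up to 4 called members of each list and a set of genes whatever their values, of which H19, 10 genes of earlier work with this compound in ovarian cancer cells, ACTB and GAPDH are given. A few genes and 1 gene list that the rule takes are not reported here, though they stayed in every test and count. Genes in the first and second parts needed a mean of at least 1 CPM and both Rg3 libraries on the same side of both controls. Other members of a gene list that the text names as examples, and genes named among the other observations, were chosen after their values were seen. Some genes stand on more than one list, such as MT2A and MT1X (metallothioneins and steroid receptor targets) and NQO1 and ABCC2 (NRF2 targets and drug transport).

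Depth ran from 24482846 counts in control 1 to 30132517 counts in Rg3 replicate 1. In 5 simulations drawn from the means and sizes of these libraries, with 200 genes changed in each, the test recovered 11.64% of 1.5-fold changes, 64.18% of 2-fold changes and 97.58% of 4-fold changes. Of 761 calls in the simulations 79 were false (10.4%), above the nominal rate, and 4.97% of unchanged genes had an unadjusted p under 0.05. Each simulation changed many genes, whereas the same test called 5 genes in the data. More calls ease the adjusted threshold, so the shares recovered may be too high for these data. A list shifted on purpose was called in 5 of 5 simulations, and 0 of 147 tests of other lists were called. Genes were drawn independently and no member of the other lists was changed, so these 0 calls do not measure false calls among correlated members.

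Alternatives were DESeq2 1.42.0, limma voom, RLE size factors, library totals alone, totals without the most abundant and small RNA, no low-count filter, a filter on a mean of at least 1 CPM, a minimum 2-fold change, the replicate number as a block, and leaving out each library in turn.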

Results

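The RNA of SKOV3 cells, a human ovarian cancer cell line, was compared between 2 control libraries and 2 libraries from cells given 80 µg/mL of the ginseng saponin 20(S)-Rg3 for 24 h. The study set out to find which RNAs, long non-coding RNAs in particular, differ after the exposure. The control libraries held 24482846 and 26731913 counts, and the Rg3 libraries held 30132517 and 24571619. Between 21917 and 22776 genes had at least 1 count in a library. Protein-coding genes took 57.17% to 59.78% of the counts, small nucleolar RNA 14.48% to 16.48%, mitochondrially encoded RNA 7.208% to 9.424%, and long non-coding RNA 0.601% to 0.6565%. The small nucleolar RNA SNORD3A alone took 10.74% to 12.22%.

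The Rg3 libraries differed from each other more than the control libraries did. Across genes, Pearson's r of log2 CPM was 0.9891 between the controls and 0.9807 between the Rg3 libraries, against 0.983 to 0.9865 for the pairs across groups. Genes are not independent replicates, so these values describe the libraries only. The first principal component, with 43.9% of the variance, placed Rg3 replicate 1 at 25.3 and Rg3 replicate 2 at −37.2, with the controls at 12.6 and −0.732. The second component, with 34.4%, placed the Rg3 libraries at 26.5 and 13.3 and the controls at −15.3 and −24.4. Counts of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 9.897 between the controls and 48.82 between the Rg3 libraries.

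In cells given Rg3, 5 genes of cholesterol synthesis were called higher with edgeR. MSMO1, which encodes a sterol C4 methyl oxidase, rose 4.10-fold, from 20.7 ± 2.25 to 85.1 ± 0.661 CPM (mean ± SD, n = 2 per group here and below). HMGCS1, which encodes the synthase that makes HMG-CoA, rose 4.41-fold, from 66.2 ± 6.47 to 292 ± 47.1 CPM. IDI1, the isopentenyl diphosphate isomerase, rose 3.36-fold to 277 ± 21.5 CPM, and SQLE, the squalene epoxidase, rose 3.30-fold to 151 ± 7.07 CPM. CYP51A1, the lanosterol demethylase, rose 2.52-fold, from 48.1 ± 1.30 to 121 ± 0.00147 CPM. CYP51A1 has processed pseudogenes that could share its reads. Of these CYP51P1 had 112 and 127 counts in controls and 358 and 255 with Rg3, and CYP51P2 had 28 and 36, then 98 and 57. These rises argue against reads having moved from the pseudogenes to CYP51A1.

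These 5 genes were the only ones of 16323 tested that passed the adjusted threshold in edgeR's quasi-likelihood test, all of them higher with Rg3, and 0 genes were called lower. Their log2 fold changes were 2.04 (SE 0.15) for MSMO1, 2.14 (SE 0.17) for HMGCS1, 1.75 (SE 0.14) for IDI1, 1.72 (SE 0.13) for SQLE and 1.33 (SE 0.13) for CYP51A1. The edgeR adjusted p was 0.010 for the first 4 and 0.036 for CYP51A1. At an unadjusted p under 0.05 there were 299 genes higher and 473 lower, 772 in all against 816 given by chance. DESeq2 called 39 genes higher and 18 lower, and limma voom called 5 and 0. Without control 1 edgeR called 42 higher and 66 lower, without control 2 31 and 18, without Rg3 replicate 1 428 and 456, and without Rg3 replicate 2 307 and 150. All 5 genes were called in each of these fits.

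A further 4 genes among the 10 with the smallest p did not pass in this test. DESeq2 and edgeR without a low-count filter called each of them, at nearly the same log2 fold changes. Over the edgeR fits that left out 1 library, log2 fold changes ran from −1.89 to −1.50 for BOLA2 and −2.42 to −1.78 for RN7SL7P. Those of INSIG1 and FDFT1 ran from 1.28 to 1.55 and from 1.11 to 1.18. INSIG1, a sterol-regulated protein that holds back the processing of SREBP, had 98.6 ± 12.3 CPM in controls and 262 ± 31.5 with Rg3 (adjusted p = 0.060). FDFT1, the squalene synthase, had 176 ± 5.95 and 389 ± 12.5 CPM (adjusted p = 0.060). The 7SL pseudogene RN7SL7P had a log2 fold change of −2.14 (SE 0.24, adjusted p = 0.060), and it can share reads with the abundant 7SL RNA genes. BOLA2 had a log2 fold change of −1.69 (SE 0.18, adjusted p = 0.059). Its near-identical copy BOLA2B had 357 and 330 counts in controls and 950 and 1019 with Rg3, where BOLA2 had 852 and 881, then 281 and 289. The values of the single copies are therefore uncertain.

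All 25 members of the cholesterol biosynthesis list were measured, of which 24 had a positive and 1 a negative log2 fold change, with a median of 1.23. Over all genes tested edgeR called 5 members, while DESeq2 and edgeR without a low-count filter called 20 each. In the main edgeR test 21 were higher when adjusted over the list alone. Those that did not pass included PMVK, LPIN1 and ACAT2, the last at 0.49 CPM in controls. The list ranked above other genes with camera (adjusted p = 1.139e-31). With the correlation between its members estimated (0.188) the call was lost (camera p = 0.02938, adjusted p = 0.6789), in a test with 2 residual degrees of freedom. In the 4 pairs of an Rg3 and a control library the median of the list lay between 0.998 and 1.40.

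**Figure D1:**
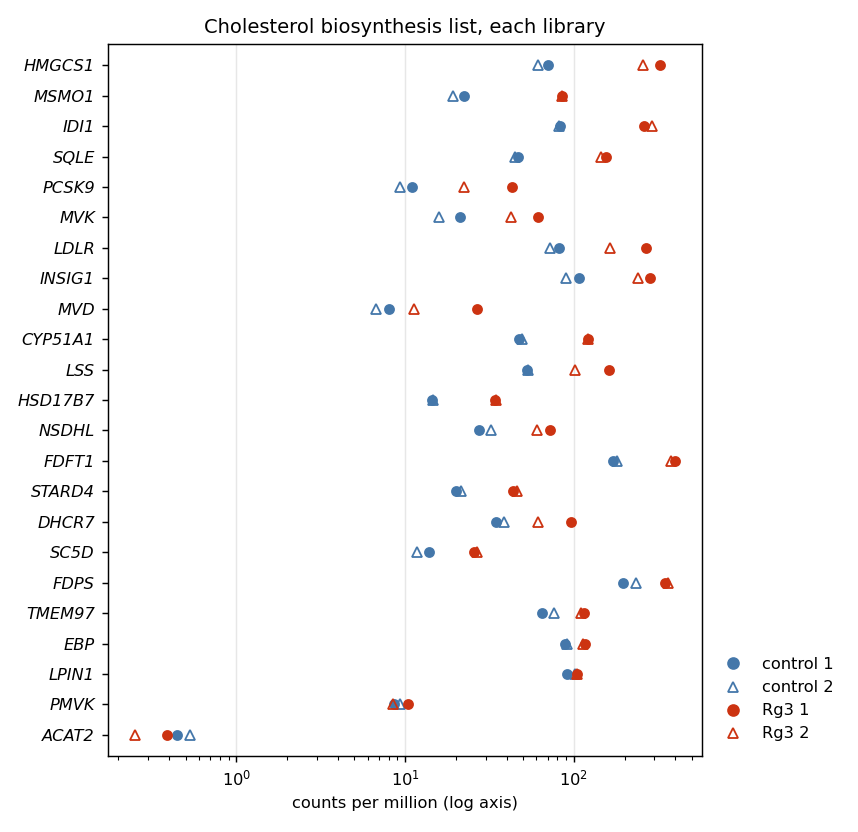
Counts scaled to a common library size (CPM), on a log axis, of 23 members of the cholesterol biosynthesis list in each library, sorted by log2 fold change. Blue marks stand for the controls and red marks for the Rg3 libraries, with a filled circle for replicate 1 and an open triangle for replicate 2. Both red marks lie to the right of both blue marks for 21 of the 23 genes drawn.

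Of 780 long non-coding RNA genes tested, 0 were called higher and 0 lower with edgeR. At an unadjusted p under 0.05 there were 12 higher and 27 lower, 39 in all, the number given by chance, and 0 passed when adjusted over long non-coding RNA alone. DESeq2 called 1 higher (C6orf223) and 1 lower (H19). H19, an imprinted long non-coding RNA and the host of a microRNA, was at 372 ± 17.6 CPM in controls and 178 ± 3.48 with Rg3, a log2 fold change of −1.06 (SE 0.13). Its adjusted p was 0.083 with edgeR, 3.568e-08 with edgeR without a low-count filter, 0.07757 with voom and 1.875e-07 with DESeq2. The log2 fold change was −1.05 both with DESeq2 and without the filter, so the smaller p-values did not come from a larger change. In the edgeR fits that each left out 1 library the adjusted p of H19 was 0.1086 without control 1, 0.086 without control 2, 0.0005832 without Rg3 replicate 1 and 0.0004018 without Rg3 replicate 2. Counts of called long non-coding RNA without these libraries were 2 higher and 3 lower, 2 and 0, 3 and 9, and 5 and 3, in the same order.

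The other long non-coding RNAs with the smallest p in each direction did not pass in this test either. C6orf223 was at 16.4 ± 1.38 CPM in controls and 36.9 ± 7.11 with Rg3 (log2 fold change 1.17, SE 0.18, adjusted p = 0.19). It passed in edgeR without a low-count filter (adjusted p = 1.289e-07), at a log2 fold change of 1.18. Its log2 fold change was 0.97 without Rg3 replicate 1 and 1.36 without Rg3 replicate 2. MIR22HG, the host gene of a microRNA, was at 25.4 ± 3.17 and 34.0 ± 0.480 CPM. LOC645553, LOC101927541 and NPPA-AS1 had log2 fold changes of 0.85, 1.20 and 0.98 at group means below 6 CPM. Without Rg3 replicate 2 the log2 fold changes of LOC645553 and NPPA-AS1 were 1.08 and 1.33, and without Rg3 replicate 1 they were 0.57 and 0.49. The log2 fold change of LOC101927541 was 0.78 without control 1 and 1.84 without control 2. On the lower side LINC00162 was at 24.9 ± 1.59 and 17.7 ± 1.88 CPM, with a log2 fold change of −0.49 (−0.60 without Rg3 replicate 1). SRRM2-AS1, LOC100287042 and LOC285696 had log2 fold changes of −0.98, −0.86 and −0.80 at group means below 5 CPM. The strand of counting is unknown, so the values of NPPA-AS1 and SRRM2-AS1 can include reads of the genes they overlap.

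Genes studied earlier with this compound in ovarian cancer cells, other than H19, did not pass, each with an adjusted p of 0.999 or above. PKM, a pyruvate kinase of glycolysis, was at 2991 ± 8.78 CPM in controls and 2697 ± 20.5 with Rg3 (log2 fold change −0.15, SE 0.13). HK2, a hexokinase, was at 14.5 ± 0.168 and 14.6 ± 5.23 CPM, and LDHA, a lactate dehydrogenase subunit, had a log2 fold change of 0.04 (SE 0.15). HIF1A, a hypoxia-responsive transcription factor, had a log2 fold change of −0.24 (SE 0.14), and STAT3 had 0.23 (SE 0.15). STAT3 was at 0.087 without Rg3 replicate 1 and 0.37 without Rg3 replicate 2, and HIF1A at −0.14 without Rg3 replicate 1. The epithelial cadherin CDH1 was low, at 1.96 ± 0.153 and 2.28 ± 0.224 CPM (log2 fold change 0.22, and 0.14 without control 2 and 0.11 without Rg3 replicate 1). VIM and SNAI1, mesenchymal markers, had log2 fold changes of 0.04 (SE 0.13) and 0.26 (SE 0.33). DNMT3A, a DNA methyltransferase, had −0.21 (SE 0.34), and VHL was at 59.9 ± 0.176 and 60.0 ± 2.75 CPM. The reference genes ACTB and GAPDH had log2 fold changes of −0.12 (SE 0.15) and −0.02 (SE 0.15), with ACTB at −0.066 without control 2, −0.23 without Rg3 replicate 1 and −0.020 without Rg3 replicate 2. The signs of HK2, LDHA, VIM, SNAI1, DNMT3A, VHL and GAPDH each turned in at least 1 fit that left out a library.

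**Figure D2:**
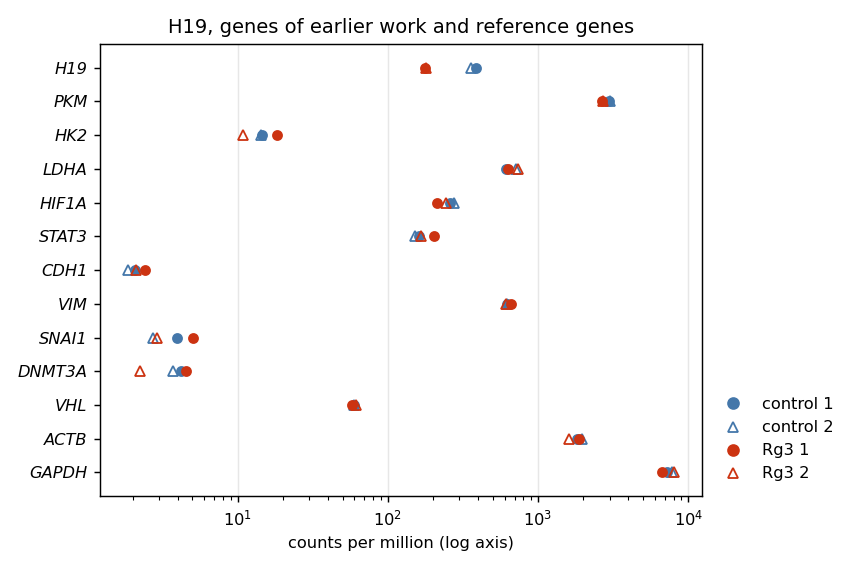
Counts scaled to a common library size (CPM), on a log axis, of H19, 10 genes of earlier work with the compound and 2 reference genes in each library. Blue marks stand for the controls and red marks for the Rg3 libraries, with a filled circle for replicate 1 and an open triangle for replicate 2. H19 lies at 384 and 359 in the controls and at 176 and 181 with Rg3.

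Of 31 gene lists tested, 12 were called with camera, 7 ranking higher and 5 lower with Rg3. With an estimated correlation 0 were called, and fry's directional test called 0, with a smallest adjusted p of 0.2038. With an estimated correlation camera rests on the 2 residual degrees of freedom, so a lost call does not show that correlated members made it. The LXR and lysosome lists lost theirs at estimated correlations of −0.0618 and −0.0378, below the preset 0.01. Fry's test for change in either direction called 4 lists, which were cholesterol biosynthesis, lysosome and autophagy, hypoxia response and cancer-associated long non-coding RNA (adjusted p = 0.02824 each). Only the cholesterol and fatty acid lists were called in every fit that left out 1 library, and the other 10 lost the call in at least 1 such fit. Over those fits the list median ran from 1.09 to 1.33 for cholesterol biosynthesis but from 0.16 to 0.44 for fatty acid synthesis. Outside the cholesterol list no member of any list was called over all genes tested in edgeR's main test. DESeq2 did call members of other lists over all genes, with adjusted p from 1.875e-07 (H19) to 0.0478 (MT1E). Among them were SCD, ACSS2, ABCA1, NEU1, DDIT3, BHLHE40, AKR1B10 and CLDN7.

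The fatty acid synthesis list had 13 of 14 tested members above 0 and a median log2 fold change of 0.25 (adjusted p = 3.299e-04, and adjusted p = 0.6978 with an estimated correlation). Adjusted over the list alone 2 members were higher. They were ACSS2, an acetyl-CoA synthetase (18.7 ± 0.376 and 34.3 ± 4.34 CPM), and SCD, the stearoyl-CoA desaturase (167 ± 57.5 and 325 ± 20.7 CPM). The median of the list was 0.44 without control 2 and 0.16 without Rg3 replicate 1. FASN, the fatty acid synthase, was at 97.3 ± 6.43 CPM in controls and at 281 and 99.5 CPM in the Rg3 libraries. Targets of LXR, a nuclear receptor activated by oxysterols, had 6 of 7 members below 0 and a median of −0.53 (adjusted p = 2.090e-03, and adjusted p = 0.6789 with an estimated correlation). The cholesterol exporter ABCA1 was at 3.33 and 11.4 CPM in controls and at 0.941 and 1.99 with Rg3, and was lower when adjusted over the list alone. Without Rg3 replicate 2 the LXR call was lost (adjusted p = 0.08673) at a median of −0.50.

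The metallothionein list had all 5 tested members below 0 and a median of −0.93 (adjusted p = 1.757e-04, and adjusted p = 0.6789 with an estimated correlation). MT1E, MT1F and MT2A, which encode metal-binding proteins, were lower when adjusted over the list alone. MT2A was at 54.0 and 88.9 CPM in controls and at 32.8 and 45.2 with Rg3. Control 1 minus control 2 had a median log2 difference of −0.70 over this list, and the call was lost without Rg3 replicate 1 (adjusted p = 0.06407). The median of the list was −0.47 without control 2 and −1.50 without Rg3 replicate 2. The drug transport and xenobiotic metabolism list had all 12 members below 0 and a median of −0.23 (adjusted p = 2.037e-03, and adjusted p = 0.6978 with an estimated correlation). Its call was lost without control 1 (adjusted p = 0.341) and without Rg3 replicate 2 (adjusted p = 0.0912). Its median was −0.065 without control 1, −0.45 without control 2 and −0.48 without Rg3 replicate 1. In this list ALDH3A1, an aldehyde dehydrogenase, was at 16.1 ± 4.37 and 8.41 ± 1.33 CPM, and 0 members passed when adjusted over the list alone.

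The integrated stress response list had 20 of 24 members above 0 and a median of 0.19 (adjusted p = 4.824e-03, and adjusted p = 0.6978 with an estimated correlation). DDIT3, which encodes the stress-induced transcription factor CHOP, was at 24.1 ± 2.58 and 42.6 ± 3.62 CPM and was higher when adjusted over the list alone. Rg3 replicate 1 minus Rg3 replicate 2 had a median of 0.373 over this list, and the call was lost without control 2 (adjusted p = 0.06776) and without Rg3 replicate 1 (median 0.031, adjusted p = 0.5916). The NF-kB and inflammatory list had 11 of 12 members above 0 and a median of 0.32 (adjusted p = 3.176e-03, and adjusted p = 0.6978 with an estimated correlation). The adhesion receptor ICAM1 was at 49.5 ± 6.17 and 75.9 ± 18.4 CPM, and 0 members passed when adjusted over the list alone. This call too was lost without control 2 (adjusted p = 0.06776) and without Rg3 replicate 1 (median 0.12, adjusted p = 0.2348), and the same difference between the Rg3 libraries was 0.361.

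Lysosome and autophagy genes had 18 of 23 members above 0 and a median of 0.13 (adjusted p = 1.338e-02, and adjusted p = 0.6789 with an estimated correlation). Adjusted over the list alone 2 were higher, the sialidase NEU1 (35.9 ± 5.25 and 66.0 ± 2.10 CPM) and the lysosomal cholesterol transporter NPC1 (27.6 ± 0.842 and 41.6 ± 3.21 CPM). The call was lost without control 1 (adjusted p = 0.1008), control 2 (adjusted p = 0.06893) or Rg3 replicate 1 (adjusted p = 0.1834), and without a low-count filter (adjusted p = 0.05389). The glucocorticoid and steroid receptor target list had 10 of 14 members below 0 and a median of −0.16 (adjusted p = 4.166e-02, and adjusted p = 0.6978 with an estimated correlation). ZBTB16, a transcription factor gene, was at 25.7 ± 1.14 and 14.6 ± 3.07 CPM and was lower when adjusted over the list alone. The call was lost without Rg3 replicate 1 (adjusted p = 0.1834) or Rg3 replicate 2 (adjusted p = 0.254), and without control 2 the median was 0.013 (adjusted p = 0.6305). Without control 1 the median was −0.25, and without a low-count filter the call was lost (adjusted p = 0.07741).

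The remaining 3 called lists also differed between replicates, and 0 of their members passed when adjusted over the list alone. Genes of G2/M and mitosis had 26 of 28 members above 0 and a median of 0.15 (adjusted p = 3.020e-03, and adjusted p = 0.7986 with an estimated correlation). BIRC5, which encodes survivin, was at 129 ± 0.785 and 160 ± 0.953 CPM. Replication-dependent histones had 15 of 18 members above 0 and a median of 0.14 (adjusted p = 9.319e-03, and adjusted p = 0.7896 with an estimated correlation). Rg3 replicate 1 minus Rg3 replicate 2 had a median of −0.224 and −0.276 over these lists. Without Rg3 replicate 2 both calls were lost, at medians of 0.033 and 0.0080 (adjusted p = 0.4827 and 0.6049), and without Rg3 replicate 1 the medians were 0.26 and 0.29. They were also lost without control 1 (adjusted p = 0.1438 and 0.08289), and the histone call without control 2 (adjusted p = 0.07533). Mitochondrially encoded RNA had 14 of 15 members below 0 and a median of −0.17 (adjusted p = 4.166e-02, and adjusted p = 0.8662 with an estimated correlation). Replicate 1 minus replicate 2 had a median of −0.45 in the controls and 0.289 in the Rg3 libraries over that list. Without control 2 its median was 0.018 (adjusted p = 0.8122) and without Rg3 replicate 2 it was −0.051 (adjusted p = 0.9249), against −0.41 without control 1 and −0.33 without Rg3 replicate 1. Its call was also lost without a low-count filter (adjusted p = 0.1054).

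**Figure D3:**
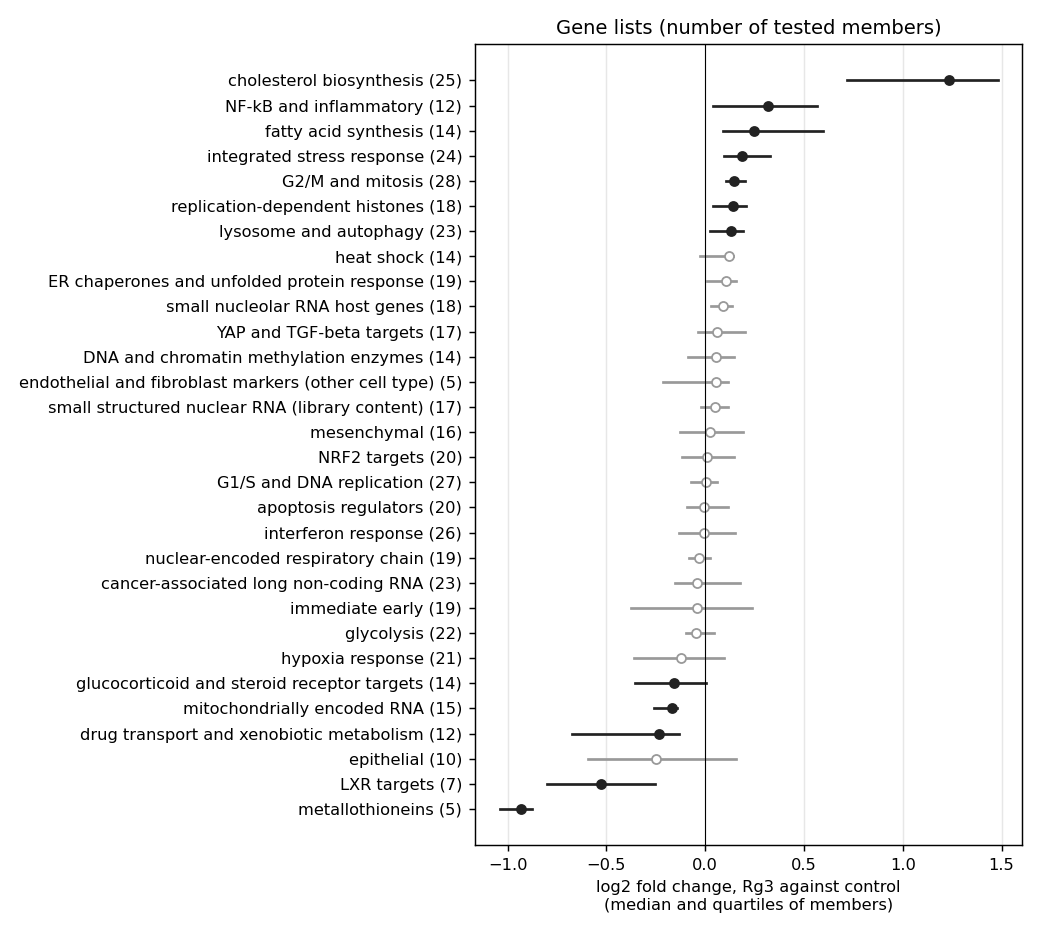
Median log2 fold change, Rg3 against control, of the members of each of 30 gene lists, with lines from the lower to the upper quartile and the number of tested members in brackets. Filled black points mark the 12 lists called with camera at the preset correlation and open grey points the others. The cholesterol biosynthesis list lies at 1.23 and the next highest at 0.32.

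With all 4 libraries and the count filter, camera did not call the other lists. The hypoxia response had 14 of 21 members below 0 and a median of −0.12 (adjusted p = 0.09706), and was called with a filter on a mean of at least 1 CPM (median −0.15, adjusted p = 0.02662). Adjusted over the list alone CA9, a carbonic anhydrase, and ANGPTL4 were lower, with log2 fold changes of −1.84 (SE 0.39) and −1.35 (SE 0.36), and BHLHE40, a circadian transcription factor, was higher at 1.10 (SE 0.26). Glycolysis had 13 of 22 members below 0 and a median of −0.04 (adjusted p = 0.8917), with 0 members passing when adjusted over the list alone. The mesenchymal list had a median of 0.02 (adjusted p = 0.8917) and the epithelial list −0.25 (adjusted p = 0.4365), where the tight junction gene CLDN7 was lower when adjusted over the list alone (34.7 ± 5.29 and 18.7 ± 4.12 CPM). Cancer-associated long non-coding RNA had a median of −0.04 (adjusted p = 0.4365), and H19 was the member that passed when adjusted over the list alone. H19 was put on this list because of earlier work with the compound. NRF2 targets had a median of 0.01 and a mean of −0.07 (adjusted p = 0.8416), with AKR1B10, an aldo-keto reductase, lower when adjusted over the list alone.

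Medians lay at 0.10 for ER chaperones (adjusted p = 0.1261), 0.12 for heat shock (adjusted p = 0.266) and 0.09 for small nucleolar RNA host genes (adjusted p = 0.4365). They were 0.06 for YAP and TGF-beta targets (adjusted p = 0.4365), 0.06 for DNA and chromatin methylation enzymes (adjusted p = 0.7131) and −0.03 for the nuclear-encoded respiratory chain (adjusted p = 0.8112). Apoptosis regulators and interferon response genes had medians of −0.0033 and −0.0037 (adjusted p = 0.8917 each). G1/S genes and immediate early genes had medians of 0.0029 and −0.04 (adjusted p = 0.9987 each), and the mean of the G1/S genes was −0.0065. Small structured nuclear RNA had a median of 0.05 and a mean of −0.06 (adjusted p = 0.8416). Markers of endothelial cells and fibroblasts were mostly absent from the tested genes, with 5 of 14 passing the count filter, a median of 0.06 and a mean of −0.23 (adjusted p = 0.7131). The muscle filament gene DES was lower when adjusted over that list alone, at 0.903 and 0.287 CPM. Of 18 immune cell markers 2 passed the count filter, CD68 and CSF1R, which are too few for a set test, with log2 fold changes of −0.45 and −0.67. Other lists were called only in some fits. Without control 1 the endothelial and fibroblast markers ranked lower, with 8 members tested (adjusted p = 0.0001018), and without control 2 ER chaperones ranked higher (median 0.19, adjusted p = 0.0365). Small structured nuclear RNA ranked higher without Rg3 replicate 1 (median 0.35, adjusted p = 0.04288) and lower without Rg3 replicate 2 (median −0.23, adjusted p = 0.002694). Small nucleolar RNA host genes ranked higher without Rg3 replicate 1 (median 0.26, adjusted p = 0.007527), and immediate early genes without Rg3 replicate 2 (median 0.10, adjusted p = 0.03691). Without a count filter the immune list, with 11 members tested, and the endothelial and fibroblast list, with 10, ranked lower (adjusted p = 0.02484 and 0.0472). The direction of the camera test with all libraries and the count filter differed in sign from the median for the endothelial and fibroblast, small structured RNA, NRF2, interferon and immediate early lists. For the mesenchymal and G1/S lists the direction of fry, but not of camera, differed in sign from the median.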

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

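The 5 genes called higher were called in all 13 alternatives to the gene test, and the cholesterol list was called in each alternative that kept camera's preset correlation. The 2-fold minimum only filters the main fit, where these genes had log2 fold changes of 1.33 to 2.14, so that outcome was fixed. Counts stayed at 5 higher and 0 lower with RLE factors, library totals alone, totals without abundant and small RNA, a mean of at least 1 CPM, limma voom and a 2-fold minimum. DESeq2 called 39 higher and 18 lower, with 1 and 1 long non-coding RNA. Without a low-count filter there were 90 and 124, with 3 and 5 long non-coding RNA. In that fit H19 (−1.05) and the cholesterol list median (1.24) lay near their main values (−1.06 and 1.23). The smaller gene p-values there thus came without larger changes. With the replicate block there were 69 and 86, with 1 and 2 long non-coding RNA. The numbers 1 and 2 were not shown to pair the libraries, since same-numbered deviations correlated at 0.149 over only 2 pairs. The block called H19 (adjusted p = 3.497e-05), C6orf223, BOLA2, RN7SL7P, INSIG1 and FDFT1, and ended the call of mitochondrial RNA (adjusted p = 0.08494). Leaving out 1 library gave 31 to 428 higher and 18 to 456 lower, with 2 to 5 and 0 to 9 long non-coding RNA, and the spread then comes from the group that kept both libraries. Gene lists called numbered 11 to 13 in the other alternatives with the preset correlation, 7 to 9 without 1 library, 0 with an estimated correlation and 0 with fry's directional test. In 6 of these alternatives 1 or 2 lists outside the 12 were called. The cause of the other shifts was not tested. Signs turned for VHL with the mean filter (−0.0039) and HK2 with the replicate block (−0.030). Over the fits without 1 library, log2 fold changes ran from −0.41 to 0.33 for HK2, −0.080 to 0.16 for LDHA, −0.17 to 0.11 for GAPDH, −0.018 to 0.097 for VIM, −0.20 to 0.60 for SNAI1, −0.82 to 0.20 for DNMT3A and −0.045 to 0.051 for VHL. List medians ran from −0.25 to 0.013 for steroid receptor targets and from −0.41 to 0.018 for mitochondrial RNA. Over named genes and alternatives, 291 comparisons kept direction and side of the threshold, 39 newly passed and 11 turned sign. For called lists these were 95 unchanged, 23 lost and 2 turned. At 2 libraries per group, 11.64% of simulated 1.5-fold changes were recovered, so absent calls do not show absent changes.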

Other observations

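DESeq2 called 57 genes, 20 of them on the cholesterol list and 8 of them pseudogenes. The genes given with values here did not pass in edgeR's treatment-only test of all 4 libraries with the count filter, and they were chosen after their values were seen. The secreted phospholipase gene PLA2G3 had 27 and 24 counts in controls and 154 and 77 with Rg3 (DESeq2 adjusted p = 0.005098). MMAB, which shares a promoter region with the mevalonate kinase gene MVK, was at 33.7 ± 0.767 and 55.1 ± 3.64 CPM (mean ± SD, n = 2 per group, DESeq2 adjusted p = 0.03483). AP1M2, a clathrin adaptor subunit of epithelial cells, was at 29.8 ± 1.59 and 52.6 ± 0.862 CPM (DESeq2 adjusted p = 0.004772). Lower were PDK4, a pyruvate dehydrogenase kinase (28.7 ± 1.26 and 13.6 ± 2.51 CPM, DESeq2 adjusted p = 0.001369), and TLE6 (30.3 ± 0.0893 and 15.9 ± 0.634 CPM, DESeq2 adjusted p = 0.003444). C11orf86 was at 209 ± 8.76 and 117 ± 10.3 CPM (DESeq2 adjusted p = 0.0008408). SREBF2, which encodes the main transcription factor of cholesterol synthesis genes, was at 117 ± 1.34 and 158 ± 27.8 CPM and was not called by either tool. MIR675, which lies within H19, had 77 and 83 counts in controls and 44 and 43 with Rg3. It was not called by either tool (DESeq2 adjusted p = 0.9999), and its reads can be reads of H19. IGF2, the imprinted neighbour of H19, had 1 count over all 4 libraries.

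The tests below were chosen after the result was seen, except that of the LXR targets. Of the 25 sterol synthesis genes, 23 were higher in both Rg3 libraries than in both controls. Over all genes edgeR called 5 members of the list and DESeq2 called 20. The list's call was lost with an estimated correlation (adjusted p = 0.6789), in a test with 2 residual degrees of freedom. A shift from library scaling would move all genes alike, whereas the list median lay 1.22 above that of all tested genes with library totals alone. A single deviating Rg3 library would leave both of the pairs without it near 0, whereas the lowest median over the 4 pairs of libraries was 0.998. A hypothesis is that the cells sensed low sterol, for which LXR targets were predicted to fall beforehand. They ranked lower (camera adjusted p = 0.00209), which is in line with it, but the LXR call was also lost with an estimated correlation (adjusted p = 0.6789) and without Rg3 replicate 2 (adjusted p = 0.08673), where the median was −0.50 against −0.53 with all libraries. Sterol levels were not measured in these data, and culture differences between the groups remain open.

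BOLA2 and BOLA2B had log2 fold changes of opposite sign. A candidate explanation is that reads of near-identical copies were assigned differently in the 2 groups. The summed counts were 1209, 1211, 1231 and 1308, with a log2 fold change of −0.00963, and each Rg3 library lay within 0.3 of the control mean (−0.248 and 0.195), which the explanation needs. In the CBWD family CBWD5 had 576 and 475 counts in controls and 94 and 148 with Rg3, while CBWD6 had 69 and 255, then 305 and 586. The sum over 7 copies was 1366, 1377, 1110 and 1463 counts, a log2 fold change of −0.152, but the Rg3 libraries lay at −0.578 and 0.176 against the control mean, so the spread leaves the explanation open there. What would make assignment differ between the groups was not tested.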
